A study of Homo sapiens with 6 samples.

How the data were processed

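RNA was measured in 6 libraries of MCF7, an estrogen receptor-positive human breast cancer cell line, 3 from control cells and 3 from cells with FOXK2 knockdown. Per the labels' protocols, cells were grown in DMEM with fetal bovine serum, RNA was extracted with TRIzol, and libraries were made from total RNA with a SMARTER mRNA-Seq kit. How FOXK2 was knocked down, and which construct or reagent the control cells received, is not given in the sources used here. The labels number the samples 1 to 3 in each group and do not say that they came from separate cultures, so p-values measure the spread between these samples, which may be technical.

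The deposited table holds whole-number read counts per gene, not normalized, for all 6 libraries. Per the submitters' processing notes, FastQC 0.11.2, HISAT2 2.1.0 and StringTie 1.3.5 were used with the GRCh38.p13 build. The step that turned assembled transcripts into counts, the annotation release and the strand setting are not given in the sources used here. Per the series' design text, the authors compared the groups with DESeq2 1.28.1 and tested pathways by over-representation; those results were not used here. The value columns of the deposited table name the knockdown samples as knockouts, whereas the sample labels call them knockdowns; each column was matched to its sample by group and number. The table has 19866 rows, of which 3141 held no count in any library. Of the rows, 14065 (70.8%) carry a StringTie locus identifier and the rest an Ensembl identifier. A total of 848 loci have several rows, 2225 in all, and 61 symbols occur more than once. Reads of genes that share a locus or overlap could have been divided in a way that the table does not show, and without a stated strand setting a gene and its antisense partner cannot be told apart.

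Counts were compared with edgeR 4.0.16 in R 4.3.3: TMM normalization, the filterByExpr filter with its minimum count of 10 and minimum total of 15, and the quasi-likelihood F test of knockdown against control, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit used the group as its only term. The filter left 13534 genes. Levels are CPM, edgeR counts scaled by library total and TMM factor. A positive log2 fold change means higher in the knockdown, and its standard error (SE) is the absolute log2 fold change divided by the square root of F. The median biological coefficient of variation was 0.235. Total counts ran from 22316628 to 25190125 in the control libraries and from 18078519 to 24692573 in the knockdown libraries. For a gene with no count in a group, the fold is given against a floor of 3 counts over the group; floors cover counting error only.

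A total of 23 gene lists were fixed before the data were examined. They cover estrogen-induced genes, luminal identity, basal mammary cells, mesenchymal markers, fibroblasts, immune and endothelial cells, DNA replication, mitosis, p53 targets, apoptosis, the unfolded protein response, autophagy and lysosomes, glycolysis, hypoxia, nuclear-encoded oxidative phosphorylation, mitochondrial-encoded genes, sterol and lipid synthesis, interferon-stimulated genes, complexes that bind FOXK proteins, other forkhead factors, growth factor signalling, cytosolic ribosomal proteins, and immediate-early and heat shock genes. Each list was tested against all other tested genes with camera (limma 3.58.1), with a preset correlation between genes of 0.01, and again with a correlation estimated from the data. Adjustment was over the 23 lists. Members past 0.05 were counted with adjustment over all genes and with adjustment over the list alone.

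The rule for named genes was also fixed before the data were examined. It takes FOXK2 and FOXK1; the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among genes past the threshold with a mean of at least 5 CPM and no overlap between groups; and up to 3 members of each list with the smallest adjusted p. Where no member of a list passed, the 2 members with the largest mean CPM were taken. Other genes are said in the text to be chosen after their values were seen.

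Coordinates, transcript lengths and GC content came from GENCODE 29 on GRCh38, matched by symbol; 13059 (96.5%) of the tested genes had a length. Length and GC content were those of the longest protein-coding transcript of a symbol, where it had one. Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, median-of-ratios and upper-quartile scaling, no low-count filter, a filter of 5 CPM in 3 libraries, the replicate number as a block, leaving out each library, a minimum change of 2-fold, and an estimated correlation in camera. Removal of a length trend or a GC trend, scaling by library totals only, and omission of the 13 mitochondrial-encoded genes were added after the data had been seen. No libraries of a group agreed within sampling noise, with a chi-square per gene of 45.89 or more within groups.

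The tests were tried on simulated data for this comparison, with counts drawn for the 13534 tested genes and 200 of them changed. So few changed genes made the adjustment stricter than in the data, so the rates below are not the power reached there. edgeR called 0% of genes changed 1.5-fold, 8% at 2-fold, 64% at 4-fold and 88% at 8-fold, with 6 false calls among 13334 unchanged genes. DESeq2 called 4%, 44%, 90% and 96% at the same sizes, with 74 false calls. limma-voom called 0%, 8%, 68% and 86%, with 3 false calls. When a length trend was added to 12866 unchanged genes, its removal took false calls from 60 to 5. camera called the list that had been raised and 0 of 20 unchanged lists. The simulated genes were drawn independently, so this could not show false calls of lists whose members are correlated.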

Results

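Transcriptomes of MCF7 breast cancer cells were compared between 3 control libraries and 3 libraries with knockdown of FOXK2, a forkhead transcription factor that recruits corepressor complexes to DNA. Total counts were 25190125, 22316628 and 24360384 in controls 1, 2 and 3, and 18078519, 18855945 and 24692573 in knockdowns 1, 2 and 3. In each library between 14730 and 15285 genes had at least 1 count. The first principal component held 36.7% of the variance and separated the groups. The knockdowns were further apart on it (77.49, 30.52 and 25.62) than the controls (-36.56, -46.58 and -50.49), with knockdown 1 away from the other 2. Values are given below as mean ± SD over the 3 libraries of a group (n = 3), and adjusted p-values are from edgeR's quasi-likelihood test unless another test is named.

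The targeted gene was lower in every knockdown library. FOXK2 (locus MSTRG.12945; chromosome 17, 82519713 to 82644662, plus strand, GRCh38) had 160.9, 158.5 and 169.6 CPM in the controls and 34.16, 36.94 and 35.7 CPM in the knockdowns. Its mean fell from 163 ± 5.82 to 35.6 ± 1.40 CPM, which is 21.8% of control (log2 fold change -2.20, SE 0.0641, adjusted p = 0.000857). No gene had a smaller adjusted p, and other genes, among them CYP1A1, RFTN1 and HSPB8, had the same value. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Its exons overlap genes on the opposite strand, among them WDR45B, so some counts could belong to those. FOXK1, the closest paralog of FOXK2, had 41.6 ± 5.56 CPM in control and 36.8 ± 1.36 CPM in knockdown (log2 fold change -0.18, SE 0.119, adjusted p = 0.348; exact permutation p = 0.3).

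**Figure D1:**
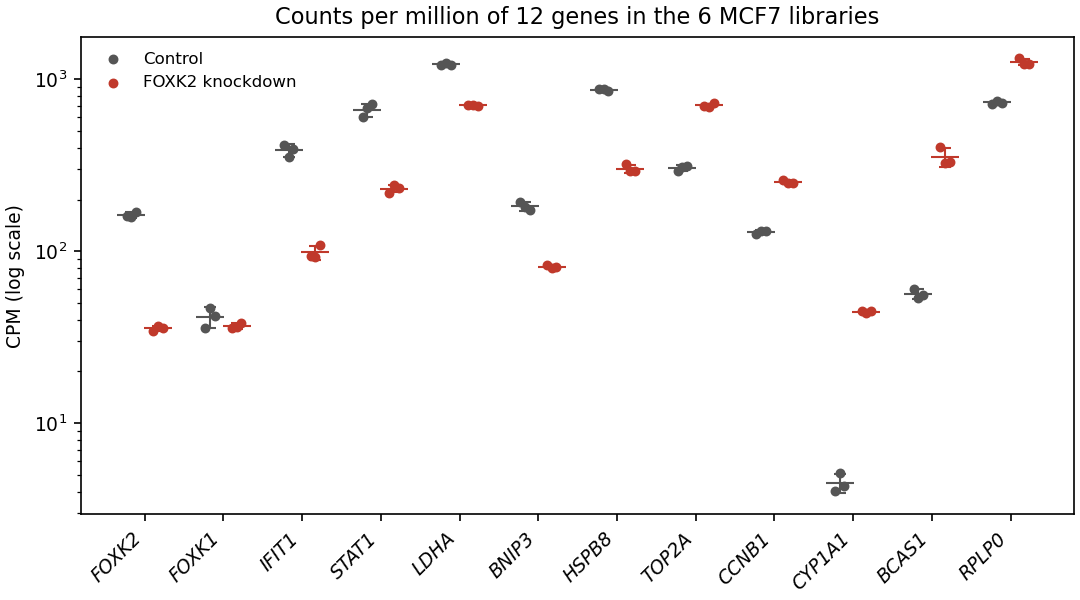
CPM (log scale) of 12 genes in each library. Points are the 3 control (grey) and 3 FOXK2 knockdown (red) libraries, horizontal bars the group means and error bars 1 SD. FOXK2 lies between 158.5 and 169.6 CPM in control and between 34.16 and 36.94 CPM in knockdown, and the groups do not overlap for any gene shown except FOXK1.

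Between knockdown and control, 2432 of 13534 tested genes (18%) differed, of which 1261 were higher and 1171 lower in the knockdown. The median log2 fold change was 0.62 among the higher genes and -0.76 among the lower ones. A total of 665 genes also changed by at least 2-fold, 288 higher and 377 lower. At an unadjusted p under 0.05 there were 4687 genes, and the groups did not overlap for 5832 genes (43.1%), against 10% by chance. The count varied with the library left out: it was 2230 without control 1, 577 without control 2, 781 without control 3, 971 without knockdown 1, 1256 without knockdown 2 and 747 without knockdown 3, and DESeq2 called 3701. With scaling by library totals only, which moved the median of all genes from -0.01 to -0.13, the split was 876 higher and 1648 lower. Calls also went with transcript length. In the shortest of 10 groups by length 20.5% of genes were higher and 3.66% lower, and in the longest 5.13% and 10.3%. With the length trend removed, over the 13059 genes with a length, 2601 genes passed, of which 2067 were among the 2432.

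The largest changes are given among genes with a mean of at least 5 CPM and no overlap between groups. Among the increases, CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, rose from 4.50 ± 0.556 to 44.5 ± 0.767 CPM (chromosome 15, 74719542 to 74725610; log2 fold change 3.31, SE 0.128, adjusted p = 0.000857). BCAS1, a gene first found as amplified in breast cancer, rose from 56.4 ± 3.76 to 353 ± 44.3 CPM (chromosome 20, 53936777 to 54070594; log2 fold change 2.65, adjusted p = 0.000929). The sialyltransferase gene ST6GALNAC2 rose from 12.1 ± 1.49 to 78.4 ± 7.25 CPM, and RFTN1, which encodes a lipid raft protein, from 3.62 ± 0.120 to 23.2 ± 0.208 CPM. USP51, a deubiquitinase gene, had no count in any control library and 10.9 ± 0.607 CPM in the knockdown, at least 272-fold higher against a floor of 3 counts over the group. Its absence from the controls could come from the counting step, so the bound is uncertain. The other leading increases were in MAPKBP1 (log2 fold change 3.31), EPB41 (3.18), JPH1 (3.16), CLASP2 (3.15) and CTD-2140B24.4 (7.75), whose locus is shared with ZNF10 and ZNF268. CTD-2140B24.4 had 517, 422 and 40 counts in the knockdowns. These 5 calls were lost in most fits with 1 library left out, although no log2 fold change fell below 2.266 in those fits. MAPKBP1 passed in no fit with 1 library left out (adjusted p 0.0532 to 0.0875). EPB41 passed only without control 1 or control 3 (0.00887 to 0.0751), JPH1 only without control 1 (0.00677 to 0.0864). CLASP2 passed only without knockdown 1 or knockdown 3 (0.0397 to 0.106) and CTD-2140B24.4 only without knockdown 3 (0.0397 to 0.11).

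The 10 largest decreases under the same limits included a cytokine gene and an interferon-stimulated gene. IL24, a cytokine gene, fell from 185 ± 18.1 to 5.82 ± 2.46 CPM (chromosome 1, 206897443 to 206904139; log2 fold change -4.99, SE 0.359, adjusted p = 0.0028). IFI44L, an interferon-stimulated gene, fell from 114.3 ± 11.04 to 2.15 ± 1.53 CPM (log2 fold change -5.70, SE 0.540, adjusted p = 0.00491). TET3, a 5-methylcytosine dioxygenase gene, fell from 42.9 ± 23.0 to 0.275 ± 0.285 CPM, and ANKRD28 from 65.2 ± 9.17 to 1.32 ± 0.543 CPM. WDR37 (log2 fold change -6.47), PCMTD2 (-5.75), MBTD1 (-4.73), PPM1E (-6.57), ZNF250 (-4.99) and UGGT1 (-4.59) were the others. All but MBTD1 and ZNF250, 8 of the 10, were at most 0.1 times their lowest control value in every knockdown library. The counting step was not excluded as the origin of such values, so the sizes of these 8 falls are uncertain. PPM1E passed only without knockdown 2 when 1 library was left out (adjusted p 0.00709 to 0.0919). ZNF250 passed only without knockdown 2 or knockdown 3 (0.0304 to 0.0955). UGGT1 lost its call without control 2, control 3 or knockdown 3 (0.0581, 0.0526 and 0.0509). Low values also arose within groups. In a single library, 243 genes in the knockdown and 159 in the control lay below 0.1 times the other 2. Those had at least 5 CPM. For 151 genes, 2 libraries of a group lay below 0.1 times the remaining one, which had at least 5 CPM. Of the 86 genes that the naming rule took, 33 have exons that overlap another annotated gene and 7 share a locus in the table. Part of their counts could belong to a neighbour.

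Interferon-stimulated genes, which encode antiviral effectors, were lower as a group. Of 35 tested members, 26 fell and 0 rose (30 and 0 adjusted over the list alone), and the median log2 fold change was -1.21. IFIT1, which encodes an antiviral RNA-binding protein, fell from 387 ± 31.7 to 98.5 ± 9.41 CPM (log2 fold change -1.97, SE 0.101, adjusted p = 0.00112). IFIT5 fell from 136 ± 6.48 to 53.4 ± 0.712 CPM, and STAT1, the transcription factor of interferon signalling, from 665 ± 58.2 to 232 ± 11.8 CPM. All 35 members had a negative log2 fold change. The list passed camera (adjusted p = 2.94e-17; adjusted p = 0.029 with an estimated correlation). Without control 2, 17 members fell.

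Genes known to be induced through the estrogen receptor were also lower as a group, while the list of luminal identity genes did not pass. Of 33 tested estrogen-induced genes, 12 fell and 1 rose (16 and 1 adjusted over the list alone), with a median log2 fold change of -0.71 (camera adjusted p = 2.01e-07; adjusted p = 0.029 with an estimated correlation). HSPB8, a small heat shock protein gene, fell from 872 ± 17.9 to 302 ± 16.5 CPM (log2 fold change -1.53, SE 0.0576, adjusted p = 0.000857). EGR3, a zinc-finger transcription factor gene, fell from 62.2 ± 3.59 to 13.4 ± 1.27 CPM. AREG, which encodes the growth factor amphiregulin, fell from 220 ± 21.1 to 83.6 ± 4.399 CPM. The member that rose, named after its value was seen, was RARA (log2 fold change 0.63, adjusted p = 0.0243), a retinoic acid receptor gene. With any library other than control 2 left out, 0 members rose. Of 24 luminal identity genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.209). AGR2 rose from 14.6 ± 1.21 to 39.2 ± 1.80 CPM, ELF3 from 46.2 ± 0.279 to 73.3 ± 1.63 CPM and MUC1 from 108 ± 3.04 to 168 ± 6.90 CPM. MUC1 shares its locus with KRTCAP2 and RP11-201K10.3. Fewer luminal genes rose without control 2, control 3, knockdown 1, knockdown 2 or knockdown 3 (3 in each case), and the median of this list was -0.04 with library totals against 0.07. ESR1, which encodes the estrogen receptor and was named after its values were seen, had 112 ± 19.7 CPM in control and 44.3 ± 24.3 CPM in knockdown and did not pass (log2 fold change -1.33, SE 0.481, adjusted p = 0.114).

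Hypoxia-inducible genes and glycolytic genes were lower in the knockdown. Of 20 hypoxia-inducible genes, 12 fell and 0 rose (13 and 1 adjusted over the list alone), with a median log2 fold change of -0.73 (camera adjusted p = 5.17e-07; adjusted p = 0.029 with an estimated correlation). NDRG1 fell from 82.7 ± 2.25 to 38.2 ± 0.235 CPM and BNIP3, a mitophagy receptor gene, from 182 ± 10.4 to 81.5 ± 1.79 CPM. P4HA1, a collagen prolyl hydroxylase gene, fell from 151 ± 11.4 to 72.4 ± 2.96 CPM. CA9, a carbonic anhydrase gene named after its values were seen, had 3.90 ± 0.128 CPM in control and no count in the knockdown, at least 76.8-fold lower against the floor. As for USP51, its absence from a group could come from the counting step, so the bound is uncertain. At that bound the list's median was again -0.73. Of 26 genes of glycolysis and of glucose and lactate transport, 11 fell and 0 rose (16 and 2 adjusted over the list alone), with a median of -0.54 (camera adjusted p = 2.6e-05; adjusted p = 0.0346 with an estimated correlation). LDHA, the lactate dehydrogenase A gene, fell from 1222 ± 16.5 to 706 ± 2.54 CPM (log2 fold change -0.79, SE 0.0401, adjusted p = 0.00112). The aldolase gene ALDOC fell from 59.8 ± 3.45 to 13.5 ± 1.59 CPM and PFKFB4 from 13.3 ± 0.730 to 4.33 ± 0.339 CPM. The glycolytic members that fell numbered 7 without control 2 or knockdown 2 and 6 without knockdown 1 or knockdown 3.

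Mitosis genes rose together, whereas the list of DNA replication genes did not pass. Of 27 mitosis genes, 18 rose and 0 fell (20 and 0 adjusted over the list alone), the median log2 fold change was 0.85 and all 27 values were positive (camera adjusted p = 1.81e-11; adjusted p = 0.029 with an estimated correlation). TOP2A, which encodes DNA topoisomerase II alpha, rose from 306 ± 10.7 to 705 ± 17.0 CPM (log2 fold change 1.21, SE 0.0498, adjusted p = 0.000869). The B-type cyclin genes CCNB1 and CCNB2 rose from 129 ± 3.34 to 253 ± 6.96 CPM and from 54.7 ± 1.01 to 103 ± 1.44 CPM. Of 30 replication genes, 4 rose and 5 fell (4 and 9 adjusted over the list alone; camera adjusted p = 0.349). This split depended on the fit: 1 rose and 11 fell with library totals, 2 and 9 with the GC trend removed, and 4 and 10 with DESeq2. RRM2 rose from 181 ± 1.22 to 251 ± 2.91 CPM, while MCM2 fell from 114 ± 4.21 to 71.7 ± 8.29 CPM and CCNE2 from 39.4 ± 8.98 to 18.7 ± 2.99 CPM. MCM2 lost its call without control 2, control 3 or knockdown 3 (adjusted p 0.0556, 0.0555 and 0.0576). CCNE2 kept it only without control 1 (0.0261, against 0.0509 to 0.0911). Among 24 p53 targets 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.169). The kinase gene PLK2 rose from 202 ± 11.5 to 475 ± 9.63 CPM and TP53I3 from 20.3 ± 1.03 to 46.6 ± 2.34 CPM. Among 23 apoptosis genes 2 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.638). The pro-apoptotic PMAIP1 fell from 9.18 ± 1.61 to 3.69 ± 0.262 CPM. With 1 library left out, as few as 1 replication gene (without control 2, control 3 or knockdown 3), 2 p53 targets (without control 2) and 1 apoptosis gene (without control 2, control 3, knockdown 1 or knockdown 3) passed.

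Transcripts of the ribosome and of the respiratory chain were higher in the knockdown, together with the mitochondrial share of all counts. Of 33 cytosolic ribosomal protein genes, 24 rose and 0 fell (30 and 0 adjusted over the list alone; median log2 fold change 0.53; camera adjusted p = 1.71e-11, but adjusted p = 0.34 with an estimated correlation). RPLP0 rose from 735 ± 14.9 to 1259 ± 55.0 CPM (log2 fold change 0.78, SE 0.0516, adjusted p = 0.00232). RPS9 rose from 222 ± 8.18 to 350 ± 28.6 CPM and RPLP1 from 557 ± 64.5 to 1027 ± 77.9 CPM. Ribosomal protein genes have many processed pseudogenes that could take a part of their reads. Of the 13 mitochondrial-encoded genes, 11 rose and 0 fell (11 and 0 adjusted over the list alone; median 0.64; camera adjusted p = 1.04e-05, but adjusted p = 0.368 with an estimated correlation). MT-ND2 went from 7828 ± 1382 to 14930 ± 1070 CPM. Of 36 nuclear-encoded respiratory genes, 11 rose and 0 fell (18 and 0 adjusted over the list alone; median 0.27; camera adjusted p = 4.53e-05, but adjusted p = 0.343 with an estimated correlation). NDUFA4 rose from 92.4 ± 3.11 to 143 ± 8.99 CPM and NDUFA1 from 80.3 ± 1.17 to 111 ± 3.82 CPM. Mitochondrial genes held 13.1% ± 1.47 of counts in control and 17.9% ± 0.608 in knockdown, and the ribosomal list 2.26% ± 0.161 and 2.98% ± 0.108. Each difference had an exact permutation p of 0.1, the smallest possible. Across the 13059 genes with a length, which are not independent replicates, the log2 fold change fell with transcript length (Spearman -0.226), and these lists hold short transcripts.

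**Figure D2:**
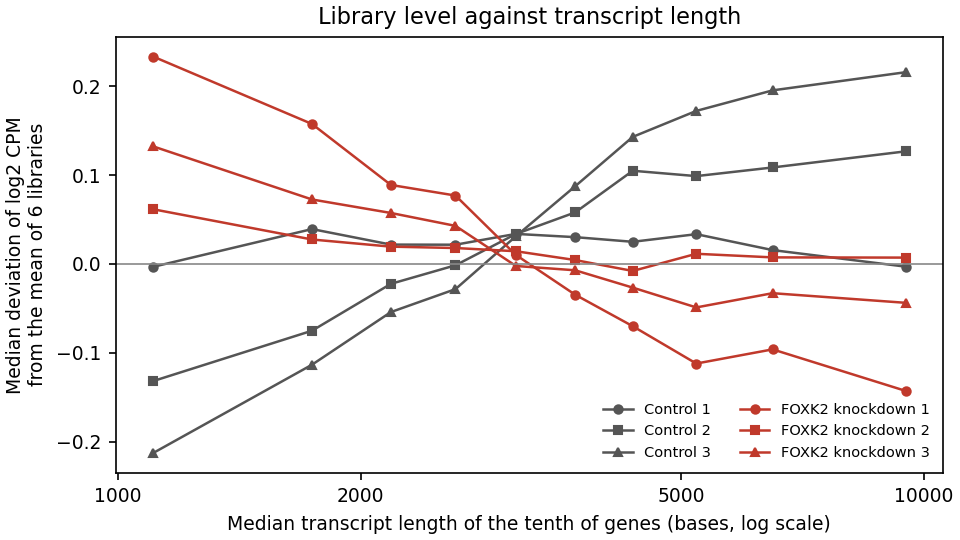
Median deviation of log2 CPM from the mean of the 6 libraries (vertical axis) against the median transcript length of genes in 10 groups by length (log scale). Lines are libraries, control in grey and FOXK2 knockdown in red. For the shortest group, knockdown 1 lies at 0.23 and control 3 at -0.21, and for the longest group they lie at -0.14 and 0.22. These are the libraries furthest apart. The Spearman correlation of the deviation with length was -0.0103, 0.214 and 0.311 in controls 1, 2 and 3. In knockdowns 1, 2 and 3 it was -0.262, -0.0288 and -0.128.

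The number of ribosomal and respiratory genes past the threshold varied with the library left out, as did the count of all genes. The list medians stayed positive in these fits. They were 0.457 to 0.603 for ribosomal proteins, 0.534 to 0.74 for mitochondrial-encoded genes and 0.195 to 0.314 for nuclear-encoded respiratory genes. Ribosomal protein genes that rose numbered 3 without control 2, 6 without control 3, 8 without knockdown 1 and 6 without knockdown 3. Mitochondrial-encoded genes that rose numbered 0 without control 2, knockdown 1 or knockdown 3, 5 without control 3 and 3 without knockdown 2. MT-ND2 had an adjusted p of 0.0658, 0.0514 and 0.0565 in the fits with 0. Nuclear-encoded respiratory genes that rose numbered 2 without control 2, 3 without control 3 or knockdown 3, 5 without knockdown 1 and 7 without knockdown 2. They numbered 6 with library totals only or with the length trend removed, where 1 member fell.

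**Figure D3:**
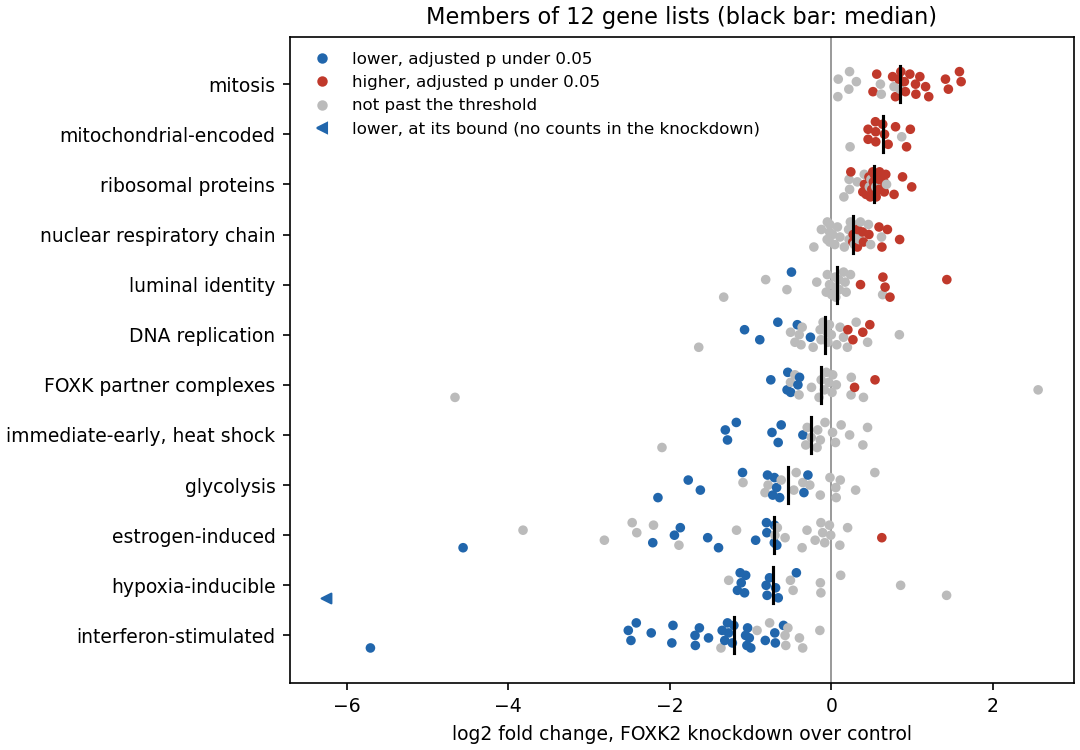
Log2 fold change (horizontal axis) of each tested member of 12 gene lists, ordered by the list's median (black bar). Blue and red points are lower and higher members past an adjusted p of 0.05 and grey points are not past it. Interferon-stimulated genes have the lowest median, -1.21, and mitosis genes the highest, 0.85. CA9 is drawn as a triangle at its bound.

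Immediate-early and heat shock genes were lower in part. Of 21 members, 7 fell and 0 rose (7 and 0 adjusted over the list alone), with a median log2 fold change of -0.25 (camera adjusted p = 0.00767, but adjusted p = 0.34 with an estimated correlation). FOS fell from 11.4 ± 0.334 to 4.66 ± 0.553 CPM, EGR1 from 12.6 ± 1.36 to 5.06 ± 0.942 CPM and HSPA1B from 813 ± 40.2 to 515 ± 35.1 CPM. HSPA1B shares its locus with its near-identical copy HSPA1A, so their split is uncertain. EGR1 lost its call without control 2 (adjusted p = 0.0534). The members that fell numbered 2 without control 2 and 4 without control 3, knockdown 2 or knockdown 3.

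No other list of signalling, stress or metabolic genes passed camera. Among 25 unfolded protein response genes 5 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.863). The chaperone gene HSP90B1 fell from 1114 ± 23.4 to 822 ± 29.4 CPM. Among 28 autophagy and lysosome genes 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.844). The autophagy kinase gene ULK1 fell from 49.8 ± 3.804 to 29.04 ± 1.44 CPM. The median of this list (0.06) and the direction of its test were upward and its mean (-0.01) downward. Among 29 sterol and lipid synthesis genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.795). The fatty acid elongase gene ELOVL6 fell from 105 ± 5.88 to 74.0 ± 1.54 CPM, a call lost without control 2 (adjusted p = 0.0556). Among 24 growth factor signalling genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.795). IRS1, an insulin receptor substrate gene, fell from 149 ± 11.3 to 72.7 ± 3.72 CPM. Among 25 subunits of complexes that bind FOXK proteins 2 rose and 6 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.199). The histone deacetylase gene HDAC2 fell from 364 ± 10.6 to 217 ± 8.72 CPM. Among 16 other forkhead genes FOXM1, a regulator of mitosis genes, rose from 65.7 ± 3.45 to 135 ± 9.27 CPM and FOXO3 fell from 80.5 ± 4.94 to 54.9 ± 3.83 CPM (1 and 1 adjusted over the list alone; camera adjusted p = 0.838). FOXO3 lost its call without control 2 or control 3 (adjusted p = 0.065 and 0.0529). With 1 library left out, as few as 1 member passed of the unfolded protein (without control 2, control 3 or knockdown 3), autophagy (without control 3 or any knockdown), FOXK partner (without control 2 or knockdown 3) and forkhead lists (without control 2 or control 3). For the others the fewest were 0 of the sterol list (without control 2) and 2 of the growth factor list (without control 2 or knockdown 3).

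No list of markers of other cell types passed camera. Of 12 tested basal mammary markers 1 rose and 2 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.178). EGFR had 2.66 ± 0.261 CPM in control and 1.14 ± 0.102 CPM in knockdown, KRT17 fell from 2.90 ± 0.712 to 0.626 ± 0.273 CPM and ITGA6 rose from 3.29 ± 0.781 to 9.21 ± 2.25 CPM. Of 11 mesenchymal markers 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.795). VIM, the vimentin gene, rose from 3.97 ± 0.164 to 8.78 ± 0.991 CPM. No fibroblast marker of 3 passed (0 and 0 adjusted over the list alone; camera adjusted p = 0.76). COL1A1 had 27.2 ± 1.83 CPM in control and 29.1 ± 0.505 CPM in knockdown. COL6A3 had 5 counts in knockdown 1 against 2083 and 2486 in knockdowns 2 and 3. Of 3 immune and endothelial markers 0 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.804), VWF from 2.73 ± 0.992 to 0.980 ± 0.249 CPM. VWF passed in no fit with 1 library left out (adjusted p 0.0611 to 0.116). KRT17 lost its call without control 2, knockdown 2 or knockdown 3 (0.0687, 0.0513 and 0.0688) and ITGA6 without control 2, control 3, knockdown 2 or knockdown 3 (0.0683, 0.0776, 0.0626 and 0.0745). As few as 1 basal marker passed without control 2 or knockdown 2, and 1 mesenchymal marker without control 2, knockdown 2 or knockdown 3.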

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

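Removal of a length or GC trend, scaling by library totals and omission of the mitochondrial-encoded genes were chosen after the data had been seen. FOXK2 stayed lower and past the threshold in every fit run, with log2 fold changes from -2.31 to -2.07. The count of changed genes was 3701 with DESeq2 (1918 higher, 1783 lower), which left 852 adjusted p-values undefined, and 665 (288 and 377) with a minimum of 2-fold, a stricter rule by construction. When single libraries were left out, which leaves fewer samples, the count ranged from 577 to 2230, the higher genes from 290 to 1178 and the lower genes from 287 to 1052. In the other fits, apart from the replicate block given below, the count stayed between 2054 and 2601. In every fit the genes shared with the calls above kept their sign, for example 541 of 577 genes without control 2. Of the 83 named genes past the threshold, 49 passed without control 2, 56 without knockdown 3, 62 without control 3, 65 without knockdown 1, 66 without knockdown 2 and 76 without control 1. The camera calls that were lost were those with an estimated correlation, which was 0.545 for ribosomal proteins (adjusted p = 0.3401), 0.0986 for immediate-early genes (0.3401), 0.244 for nuclear-encoded respiratory genes (0.3432) and 0.831 for mitochondrial-encoded genes (0.3679) in place of the preset 0.01.

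Lists that did not pass changed direction without passing, and the cause was not tested: basal markers with a filter of 5 CPM (adjusted p = 0.7604), fibroblast and forkhead genes with no filter (0.9323 each), forkhead (0.9954) and growth factor genes (0.5639) with the length trend removed, and autophagy genes with library totals (0.8657). Without single libraries, sterol genes did so without control 1 (0.9895; range 0.6047 to 0.9895). The unfolded protein (0.9515; range 0.7837 to 0.955) and forkhead genes (0.9288; range 0.7728 to 0.9535) did so without knockdown 3. COL6A3, near 0 in log2 fold change, turned positive with median-of-ratios scaling (0.0002672), upper-quartile scaling (0.0009906) and the length trend removed (0.1066), and without control 2 (0.133) or knockdown 1 (0.5785), the library with 5 counts; single libraries left out gave -0.473 to 0.5785. COL1A1 turned to -0.02003 with library totals. In simulated counts of this depth and spread edgeR called 0% of genes changed 1.5-fold and 8% of those changed 2-fold. Far fewer genes were changed there than were called in the data, which made the adjustment stricter. These rates are therefore not the power reached in the data, where 665 of the 2432 called genes changed by at least 2-fold and the rest by less. The simulation does not separate the parts of depth, of spread and of the small number of changed genes.

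The data showed no clear pairing of samples by replicate number, a weak one was not excluded, and the labels do not say what the numbers mean. Deviations from the group means correlated across genes at 0.0754, -0.0456 and 0.017 for samples 1, 2 and 3. Control 1 correlated best with knockdown 1. Control 2 and control 3 correlated best with knockdown 3 and knockdown 2, not with their own number. With the replicate block the count was 1090 (563 higher, 527 lower), a fit with fewer residual degrees of freedom. The block changed no camera call, but 17 named genes lost theirs, and fewer list members passed: for example 4 mitochondrial-encoded genes rose in place of 11, 6 glycolytic genes fell in place of 11, and 1 replication gene rose and 1 fell in place of 4 and 5.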

Other observations

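Further gene lists, 9 in all, were chosen after the values had been seen, as were the genes named from them and the tests of library scaling, of the control construct and of genes prone to failed counts; the other tests were set down before their results. As the added lists were put together with values in view, their counts and p-values describe them and are not tests of a prior expectation. Of 12 tested genes linked to secretory differentiation of glandular epithelium 7 were higher and 0 lower, with a median log2 fold change of 1.12. The camera adjusted p was 4.26e-06 over the added lists, but 0.115 with an estimated correlation. BCAS1, AGR2 and MUC1, given above, are among the 7. S100P rose from 6.67 ± 0.558 to 35.4 ± 2.45 CPM, CEACAM6 from 9.62 ± 0.270 to 36.5 ± 1.66 CPM and GPRC5A from 54.3 ± 1.65 to 163 ± 8.26 CPM. Among aryl hydrocarbon receptor targets 3 of 6 rose and 1 fell (camera adjusted p = 0.0567; adjusted p = 0.298 with an estimated correlation): beside CYP1A1, CYP1B1 rose from 46.1 ± 6.32 to 199.5 ± 13.8 CPM, while TIPARP fell (log2 fold change -0.55), and 2 passed when any library other than control 1 was left out. Among insulin-like growth factor binding proteins and suppressors of cytokine signalling 4 of 12 rose and 2 fell (camera adjusted p = 0.0206, but adjusted p = 0.249 with an estimated correlation), with SOCS2 up from 9.77 ± 0.707 to 39.1 ± 2.98 CPM, IGFBP5 up from 320 ± 13.8 to 739 ± 59.8 CPM and IGFBP4 down from 443 ± 39.9 to 255 ± 16.6 CPM.

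MHC class I and interferon-gamma response genes fell in part, with 8 of 18 lower and 1 higher (camera adjusted p = 0.00512, but adjusted p = 0.144 with an estimated correlation); HLA-A went from 114 ± 8.58 to 68.3 ± 5.73 CPM and GBP1 from 7.83 ± 0.444 to 2.14 ± 0.0861 CPM, and 2 members passed without knockdown 3. HLA genes are close in sequence, so their split is uncertain. Of 16 Notch pathway genes 1 rose and 3 fell (camera adjusted p = 0.256; adjusted p = 0.31 with an estimated correlation), with NOTCH3 down from 132 ± 11.7 to 12.6 ± 3.31 CPM and ASCL1, a neuroendocrine transcription factor gene, from 64.3 ± 3.58 to 9.05 ± 0.525 CPM. Of 24 genes of histone and DNA methylation and demethylation, complex subunits included, 1 rose and 4 fell (camera adjusted p = 0.0897; adjusted p = 0.279 with an estimated correlation). Those that fell include TET3, whose fall is of uncertain size, and 2 members passed without control 2, knockdown 1 or knockdown 3. Mitochondrial ribosomal proteins (8 of 29 higher, 0 lower; camera adjusted p = 1.46e-05, but adjusted p = 0.31 with an estimated correlation), proteasome subunits (7 of 29 and 0; 0.00478, but adjusted p = 0.31) and translation factors (6 of 21 and 1; 0.00478, but adjusted p = 0.298) rose in part. Of these, 2, 0 and 1 members passed without control 2.

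Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real one, the real split itself, with 2432 genes; the highest other split gave 4. The splits are too few for a share under 0.05.

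The joint rise of ribosomal protein, mitochondrial-encoded and nuclear respiratory transcripts runs with a length trend between libraries. With that trend removed the ribosomal median was 0.303 (0.525 before; 0.256 for lists matched on length and level, among which it stood at percentile 100) and the mitochondrial-encoded median 0.3251 (0.636 before). The trend as measured thus did not take away the whole rise of these 2 lists. Length was that of the longest transcript, which may not be the one expressed. Matched lists were drawn as independent genes, whereas the estimated correlation was 0.545 for ribosomal and 0.831 for mitochondrial-encoded genes. Whether a length trend is the whole cause therefore cannot be told from this. The nuclear respiratory median, over the 31 members with a length, went from 0.315 to 0.138 (0.198 for matched lists; percentile 95.22), and for that list too the trend stays open. The lowest ribosomal median under the other scalings was 0.409. The widest shift, with library totals, took the median of all genes from -0.0116 to -0.13. So small a shift could not have taken away a median of 0.525, and this test does not decide on scaling. Within the controls the ribosomal mean ranged over 0.489 of the knockdown difference. The proteasome list ranked these 3 libraries alike, as a library quality shared by short transcripts would give. The nuclear respiratory list ranked the libraries as the ribosomal list did in both groups. The mean of the mitochondrial-encoded list, which weighs its genes alike, ranked control 3 (12.35) above control 2 (12.23). The mitochondrial share of counts, however, ranked the libraries as the ribosomal list did in both groups. It was 14.53%, 13.14% and 11.6% in controls 1, 2 and 3, and 18.49%, 17.28% and 17.79% in knockdowns 1, 2 and 3. The proteasome list ranked knockdowns 2 and 3 the other way. Library quality stays open as an explanation, and whether the knockdown adds to the rise cannot be told here.

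The fall of interferon-stimulated genes was not taken away by either technical test. With the length trend removed the list's median was -1.16, and with 1 library left out at least 17 members fell, which argues against a length trend and against a single library. A lower interferon response after loss of FOXK2 is a candidate explanation. A response raised in the control cells by their own construct is another, and these cannot be told apart, because the design holds 1 kind of control sample. Control cells of another kind would test only whether the control construct raised the response. The other gene lists rest on the same kind of control sample.

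Some genes were far lower in all libraries of one group than in the other. In the knockdown there were 11, among them TET3, WDR37, IFI44L and IL24. Each had at least 5 CPM in every control library and at most 0.1 times its lowest control value in every knockdown library. By the same rule 2 were low in the control, USP51 and TMEM106A. Not all were near 0: IL24 had 8.334, 3.428 and 5.684 CPM in the knockdowns. Independent failures of the count estimate would give 0.00502 such genes in the knockdown, and the 11 seen are 2190 times that. In the knockdown 95 genes were low in 2 of the 3 libraries, against 1.91 expected. Over both groups such genes were 11.62 times as many as those low in all 3. The rules behind these numbers differ, however. The count of 95 asks for 5 CPM only in the highest library of the group and asks nothing of the other group. It therefore also takes genes that are low elsewhere. Whether the count estimate fails at genes prone to it cannot be told from this test. A move of reads to another row of the locus was seen for 0% of the 11 genes, but none of them has another row, so that and a true loss of expression cannot be told apart here. The values of these 13 genes may therefore reflect the counting step rather than expression.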
